A study of Mus musculus with 9 samples.

How the data were processed

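RNA of sorted T cell subsets was measured with pairs of a biotinylated capture probe and a barcoded reporter probe, per the labels' protocols, which also state that total RNA was isolated with a column kit. The deposited table held log2 values of 770 gene names in 9 samples, with 2 decimals and no missing value. The counting instrument, the scaling between samples and the rule for the floor are not given in the sources used here. The lowest deposited log2 value was 4.32, the log2 of 20, in every sample. In 4 samples the low values, turned back to a linear scale, fell on whole multiples of 1 step: 3.95 normalized counts per count in intraepithelial CD4, 2.30 in intraepithelial CD4CD8, 1.66 in intraepithelial CD8 and 2.41 in lamina propria CD8, with 96.1 to 98.5% of values up to 150 normalized counts whole within 0.005 log2 of rounding, and 19.3 to 34.9% expected by chance. In these 4 samples the lowest listed value above the floor equalled 20.0 counts, so genes with fewer counts appear to have been listed at the floor whatever their scaling. Summed over genes above the floor, the steps give 48982, 137569, 136418 and 65213 counts in those samples. In the other 5 samples no step was resolved and the depth is unknown. Raw counts were not used here, so edgeR, DESeq2 and voom were not run. These sums describe counting precision only, and with 1 sample per group the number of samples limits the precision of every comparison.

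Gene names were kept as deposited. Of them 754 matched a current symbol of the RefSeq table of the mouse assembly GRCm38.p6, 8 matched a synonym and 8 matched neither. Gpr44 and Ptgdr2 name 1 gene and were both at the floor. No coordinates are given, since the file names no genome build.

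Samples were grouped by the tissue and subset of their labels. The main test was limma (version 3.58.1, R 4.3.3) with lmFit and eBayes with a mean-variance trend on the deposited log2 values of the 8 CD4 and CD8 samples, with additive terms for tissue (4 levels) and subset, which leaves 3 residual degrees of freedom (prior degrees of freedom 1.91). The design written before the data were examined assumed log2(value + 1) for linear values, and since the table was on a log scale, values were used as they were. Contrasts were CD8 minus CD4, gut minus lymph node, intraepithelial minus lamina propria and mesenteric minus peripheral. The difference of the CD8 minus CD4 difference between gut and node was tested with an added term (2 residual degrees of freedom). The residual is the variation of tissue effects with subset, since there are no replicate samples, and nothing in the labels says whether a sample was 1 animal or a pool. Genes above the floor in at least 2 of the 8 samples were tested, without 13 housekeeping genes, which left 440. P-values are two-sided and were adjusted by Benjamini-Hochberg within a comparison at a threshold of 0.05. Where 1 group was at the floor throughout, the lower bound is the mean of the other group less the mean of the lowest values above the floor in the samples at the floor.

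Gene lists (20, written before the data were examined) covered the CD4 and CD8 lineages, the T cell receptor complex, cytotoxic and NK-type genes, residence and gut homing, naive and lymph node homing, Th1, Th2, Th17 and regulatory genes, inhibitory receptors, chemokines, immediate-early and NF-kB response, interferon response, B cell, class II, myeloid, epithelial and stromal markers, common gamma chain receptors and housekeeping genes. Lists with at least 3 tested members were tested with limma's fry, adjusted over the lists of a comparison, with camera (preset correlation 0.01, and estimated correlation) as alternatives. Fry asks whether the genes of a list move 1 way on balance and does not compare the list with other genes. With an estimated correlation no list passed in any comparison. Of the listed genes, 11 belonged to more than 1 list, and a further alternative left them out.

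Named genes followed a rule written before the data were examined: Cd4, Cd8a and Cd8b1, the 10 largest called differences in each direction with the same sign in every matched pair, or all called and up to 5 more as values where fewer passed, and from each list up to 4 members with the largest difference and all called members. The text names those of them that its groups need, and 4 genes are not reported here. For the CD4CD8 sample the rule took the 10 genes farthest above and below both other intraepithelial samples by listed values, and list medians were placed among 10000 random lists matched on mean level (numpy 2.4.6, pandas 2.3.3, Python 3.11.15). Other genes of the fixed lists that the text gives as values for single samples, and Oas2, which the rule named, carry no further selection, except where the text says that a choice was made after the data were seen.

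The fit was tested on simulated data of 20 sets with 100 changed genes each. For CD8 against CD4 (median 436 genes tested) it recovered 54.7%, 78.4% and 80.9% of genes changed by 1, 2 and 3 log2, and 2.9% of its calls were false. For gut against lymph node (median 439 genes) it recovered 58.0%, 81.5% and 94.5%, and 4.2% of its calls were false. Noise was drawn from the spread of the same fit, independently between genes and samples, with no change of the subset difference between tissues. These shares therefore do not measure the error of the calls reported here. Alternatives were a pseudocount of 20, no filter, centring on sample medians or on housekeeping genes, quantile normalization, eBayes without trend, sample weights, no block, all 9 samples, each tissue pair or sample left out, and, added after the unequal detection limits were seen, a common floor of 6.30 and fits without genes at the floor in a compartment. Figures were drawn with matplotlib 3.10.9.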

Results

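Transcripts of immune genes were measured in T cells of B10.RIII mice, a strain used for experimental autoimmune uveitis, with a panel of barcoded probes. The 9 samples covered 4 tissues: the intraepithelial compartment of the gut, the small-intestinal lamina propria, the mesenteric lymph nodes and the peripheral lymph nodes. Each tissue gave 1 CD4 and 1 CD8 sample, and the intraepithelial compartment also gave 1 sample of cells labelled CD4CD8. The study concerned short and long antibiotic depletion of the gut microbiota before immunization with a retinal peptide. The sample labels name neither an antibiotic arm nor the number or genotype of mice behind each sample, so the comparisons here are between tissues and between subsets. There were no replicates: each value below is from 1 sample, and tests used the variation of a difference across tissues or subsets as the spread.

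The table held 770 genes as log2 normalized counts with a floor of 4.32. Between 336 genes (intraepithelial CD4) and 474 genes (lamina propria CD4) lay above the floor. The floor did not mean the same in every sample, since the lowest listed value above it was 6.30 in intraepithelial CD4, 5.59 in lamina propria CD8, 5.52 in intraepithelial CD4CD8 and 5.05 in intraepithelial CD8, and at most 4.38 in the other samples. A gene at the floor in 1 of those 4 samples is therefore known only to lie below that sample's limit. Folds against a group that was at the floor throughout are given as lower bounds from these limits. The fit took values at the floor as 4.32. Samples at the floor then add no spread, so the SE and adjusted p of genes with many such values can be too small. Where only some samples of a group were at the floor, a difference marked "at limits" gives the value with those samples taken at their limits, if it moved by over 0.1; this was chosen after the data were seen. The mean of 13 housekeeping genes lay between 8.41 and 8.62 in the 9 samples.

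The first comparison asked how CD8 samples differed from CD4 samples in all 4 tissues. The lineage genes matched the labels. Cd4 was 9.14 to 9.80 in the CD4 samples and at the floor in the 4 CD8 samples, at least 26.3-fold lower (log2 difference -5.23 ± 0.17, SE of the fit over 8 samples here and below; adjusted p = 0.000329, lower in 4 of 4 tissues). Cd8a, the alpha chain of the CD8 co-receptor, was at least 44.4-fold higher in CD8 samples, and Cd8b1, the beta chain, at least 22.3-fold (both adjusted p = 0.000969). Of 440 genes tested, 24 were higher and 40 lower in CD8, and all 64 had the same sign in the 4 tissues.

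Genes of cytotoxic cells and NK-type receptors were higher in CD8. Of 17 tested members of that list, 5 rose and none fell. Klrd1 and Klrc1, which encode the CD94 and NKG2A receptor chains, rose by 3.08 ± 0.28 and 3.43 ± 0.40 (Klrc1 2.915 at limits; adjusted p = 0.0055 and 0.0126). Ctsw, a protease of cytotoxic lymphocytes, rose by 2.38 ± 0.21, and Cd160, an NK-type receptor, by 2.25 ± 0.14 (adjusted p = 0.00542 and 0.00173). Perforin (Prf1), which forms pores in target cells, rose by 1.21 ± 0.22 (adjusted p = 0.0302). Gzma and Gzmb did not pass this test: the difference was 0.48 ± 0.21 for Gzma and 0.20 ± 0.15 for Gzmb (adjusted p = 0.196 and 0.417). In the nodes Gzmb was at the floor and Gzma at most 4.67, so the node pairs could show little difference. Gzma was 13.48 in CD4 and 14.67 in CD8 intraepithelial, and 9.64 and 10.01 in the lamina propria. Gzmb was 11.66 and 12.25, and 8.35 and 8.54, in the same order. The list as a whole was higher in CD8 (fry adjusted p = 0.00945), and the call was lost in camera with an estimated correlation (adjusted p = 0.206). Adjusted over the list alone, 6 members were higher.

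Chemokine transcripts followed the same direction, with 3 of 7 tested members higher and none lower. Ccl5 rose by 4.17 ± 0.71, Xcl1 by 2.90 ± 0.44 and Ccl4 by 1.74 ± 0.23 (adjusted p = 0.0246, 0.0196 and 0.0139). The list had a fry adjusted p of 0.0172, against an adjusted p of 0.255 with an estimated correlation, and 4 members were higher when adjusted over the list alone. Of 10 genes of tissue residence and gut homing, Itgae (the CD103 integrin chain) rose by 1.25 ± 0.19 and Cd160 also rose, and the same 2-gene count held adjusted over the list alone (fry adjusted p = 0.0223, adjusted p = 0.267 with an estimated correlation). Cd7, a membrane protein of T and NK cells, rose by 2.36 ± 0.25 (adjusted p = 0.00974). Eomes, a transcription factor of CD8 and NK cells, was 7.03 to 7.45 in the lamina propria and lymph node CD8 samples and at the floor in the intraepithelial CD8 sample, and did not pass the test (2.19 ± 0.60, 1.845 at limits, adjusted p = 0.0835). Cd79b, known from the B cell receptor, rose by 1.82 ± 0.36 (1.33 at limits, adjusted p = 0.0338). Of other B cell genes, Cd79a and Pax5 were at the floor in every sample. Ms4a1 (CD20) was 4.87 and 4.88 in mesenteric CD4 and CD8 and 5.59 in intraepithelial CD4CD8. Blk, Blnk and Tnfrsf13b were above the floor in some samples.

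Regulatory genes and 2 of 5 tested Th2 genes were lower in CD8, and the Th1 list did not pass (fry adjusted p = 0.894). Of 11 tested regulatory T cell genes, 7 fell, and 8 fell adjusted over the list alone (fry adjusted p = 0.00177, adjusted p = 0.206 with an estimated correlation). Foxp3, the lineage factor of regulatory T cells, was 7.38 to 8.02 in the CD4 samples and at least 7.01-fold lower in CD8 (adjusted p = 0.00173). Tnfrsf4 (OX40) fell by 3.38 ± 0.39 (-2.88 at limits), Il2ra (CD25) by 3.02 ± 0.49, Ctla4 by 2.53 ± 0.22 and Icos by 2.23 ± 0.42 (adjusted p = 0.0124, 0.0213, 0.00538 and 0.0302). Cd40lg, by which helper T cells stimulate B cells and dendritic cells, fell by 4.32 ± 0.34 (-4.125 at limits; adjusted p = 0.00369). Tnfsf11 (RANKL) fell by 3.09 ± 0.40 and Cd83 by 2.85 ± 0.44 (-2.58 and -2.67 at limits). The chemokine receptor genes Ccr6 and Ccr4 were at least 5.12-fold and 4.17-fold lower (both adjusted p = 0.0126).

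Of 5 tested Th2 genes, Ccr4 and Gata3 fell, with 3 lower adjusted over the list alone (fry adjusted p = 0.0172, adjusted p = 0.375 with an estimated correlation). Of 12 genes of the T cell receptor complex, Cd5 fell by 1.03 ± 0.08 and Cd6 by 0.51 ± 0.11 (adjusted p = 0.00369 and 0.0454). That list's fry adjusted p was 0.00977, the adjusted p with an estimated correlation was 0.891, and its median of -0.24 turned to 0.02 when samples were centred on their medians. Rora fell by 1.53 ± 0.20 among 13 Th17 genes, a list that did not pass (fry adjusted p = 0.102). Cd74, the class II invariant chain, fell by 1.63 ± 0.35 (adjusted p = 0.0451), a call that was lost with median centring, where the difference stayed at -1.37. H2-Aa, a class II chain made by antigen-presenting cells, was 5.67 to 8.33 in CD8 and 6.48 to 9.11 in CD4 samples.

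**Figure D1:**
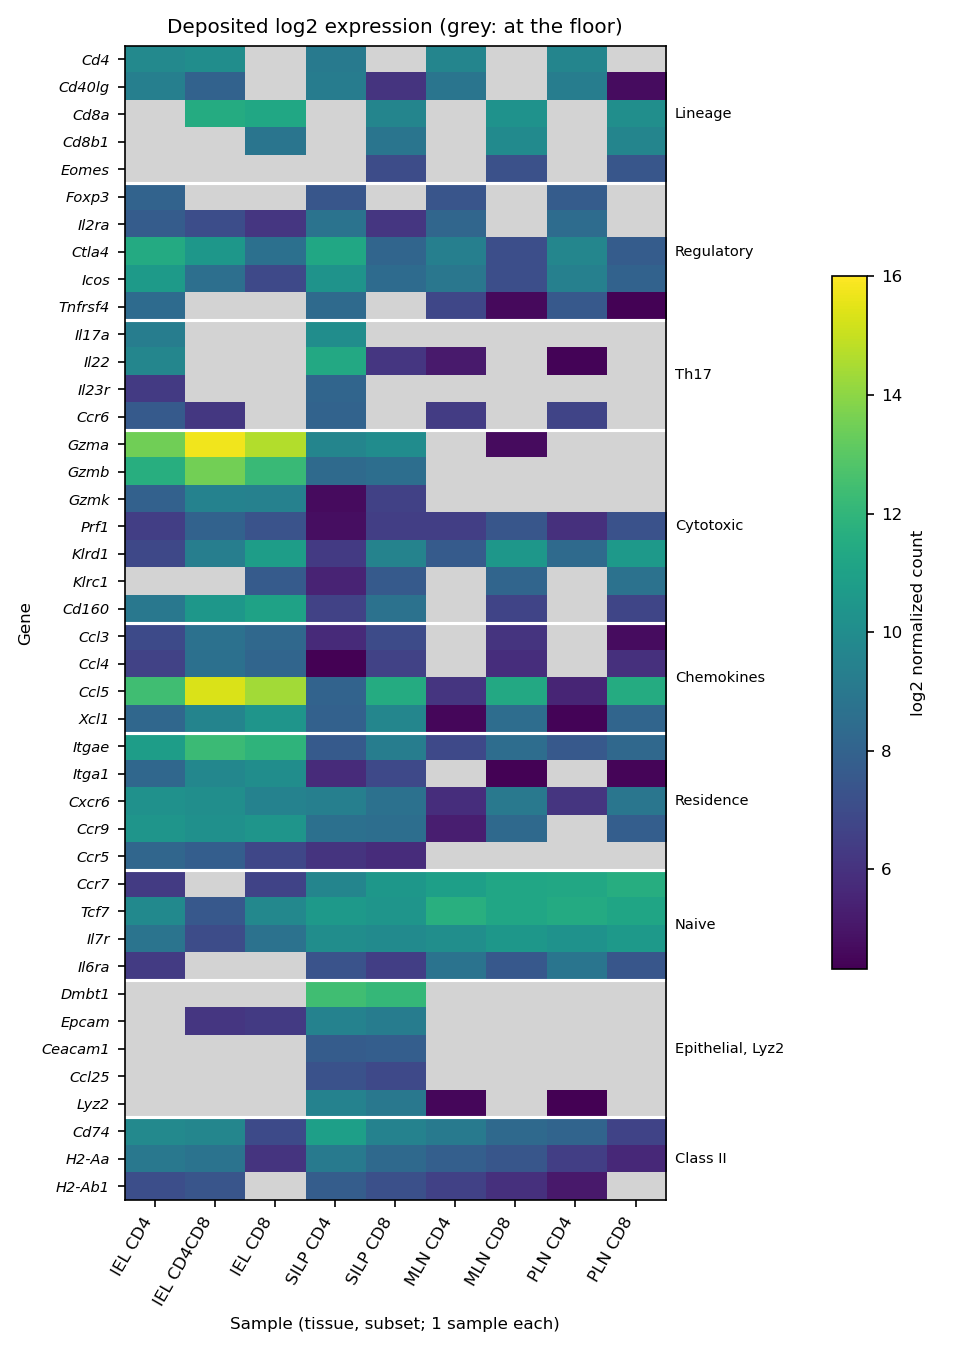
Deposited log2 normalized counts of named genes (grouped on the right) in the 9 samples (1 sample each), with grey where a gene was at the floor of 4.32. Gzma reached 15.76 in intraepithelial CD4CD8, Cd8b1 was grey there, and Dmbt1 was above the floor only in the lamina propria samples (12.42 and 12.11).

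The limma fit took the tissue as a block, and its residual was the part of the CD8 difference that varied between tissues. The count of 64 fell to 22 without the mesenteric or without the peripheral node pair and to 30 without the lamina propria pair, to 36 when all values below 6.30 were raised to it (ending the calls of Cd160, Cd79b, Ccr6, Cd83, Ccr4, Prf1, Ccl4, Cd6 and Rora), and to 14 with no filter on genes at the floor. The count rose to 158 with sample weights. With the raised floor the Cd6 difference stayed at -0.51, as no Cd6 value lay below 6.30. For Rora only mesenteric and peripheral CD8 (5.54 and 6.09) lay below it. Centring each sample on its median shifted the median difference of all tested genes from -0.14 to 0.08 and gave 62 calls, of which 62.9% were higher in place of 37.5%.

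The second comparison set the gut samples (intraepithelial and lamina propria) against the lymph node samples in both subsets. Gzma and Gzmb had the largest differences. Gzma, a granule protease, was 13.48 and 14.67 in intraepithelial CD4 and CD8, 9.64 and 10.01 in lamina propria CD4 and CD8, and at most 4.67 in the lymph nodes (log2 difference 7.54 ± 0.21, adjusted p = 8.47e-05, higher in both subsets). Gzmb was at least 57.4-fold higher in gut and Gzmk at least 6.95-fold (adjusted p = 8.47e-05 and 0.00901). Gzmk was 4.64 in lamina propria CD4, close to the floor. In all, 68 genes were higher and 57 lower in gut among 440 tested. Each tissue had its own term in the fit, so the gap between intraepithelial and lamina propria samples did not enter the SE. The same holds for the gap between the nodes. The p-values of this comparison therefore measure how far tissue differences varied with subset, and not whether a difference was shared by both gut compartments.

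Of 17 cytotoxic and NK-type genes, 6 rose and none fell, also when adjusted over the list alone (fry adjusted p = 0.00393, adjusted p = 0.521 with an estimated correlation). Cd160 rose by 3.31 ± 0.14 (adjusted p = 0.000298), and Cd244, an NK-type receptor of the SLAM family, was at least 7.63-fold higher (adjusted p = 0.0159). Of 10 residence and homing genes, 6 rose and 1 fell, with 7 and 1 adjusted over the list alone (fry adjusted p = 0.00393, adjusted p = 0.477 with an estimated correlation). Itga1, a collagen-binding integrin chain of resident T cells, rose by 3.35 ± 0.37, Itgae by 2.10 ± 0.19 and Ccr9, the receptor for the gut chemokine CCL25, by 3.05 ± 0.75 (adjusted p = 0.00492, 0.00348 and 0.0381). In CD4 samples Itgae was 10.84 intraepithelial, but 7.63 in the lamina propria against 6.91 and 7.59 in the mesenteric and peripheral nodes. Itga4, the alpha-4 integrin chain, fell by 1.38 ± 0.09 (adjusted p = 0.00127).

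Of 7 tested chemokine genes, 6 rose, with 7 adjusted over the list alone (fry adjusted p = 0.00393, adjusted p = 0.42 with an estimated correlation). Ccl5 rose by 2.96 ± 0.71, Xcl1 by 2.65 ± 0.44, Ccl3 by 2.12 ± 0.29 and Ccl4 by 1.33 ± 0.23. Ccl4 was 4.34 in lamina propria CD4, close to the floor where the node CD4 samples lay. Of 8 inhibitory receptor genes, 4 rose, among them Ctla4 by 1.41 ± 0.22 (adjusted p = 0.00969), and 6 rose adjusted over the list alone (fry adjusted p = 0.00713, adjusted p = 0.521 with an estimated correlation). Of 11 regulatory genes, 3 rose and 1 fell, with the same counts adjusted over the list alone (fry adjusted p = 0.00976, adjusted p = 0.521 with an estimated correlation). Foxp3 was not among them (0.09 ± 0.21, adjusted p = 0.726). Cd38, an ectoenzyme of activated lymphocytes, rose by 3.21 ± 0.17, and Rora, a nuclear receptor of Th17 and innate lymphoid cells, by 2.58 ± 0.20 (adjusted p = 0.000621 and 0.00242).

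Genes of naive cells and lymph node homing were lower in gut: 6 of 8 fell, also adjusted over the list alone (fry adjusted p = 0.00206, adjusted p = 0.42 with an estimated correlation). Ccr7, which guides cells into lymph nodes, fell by 2.98 ± 0.12 (adjusted p = 0.000298). Tcf7, a transcription factor of naive and memory T cells, fell by 1.22 ± 0.09 and Il7r, the IL-7 receptor chain, by 1.00 ± 0.13 (adjusted p = 0.00212 and 0.00565). St6gal1 and Cmah, enzymes of sialic acid metabolism, fell by 2.27 ± 0.24 and 2.49 ± 0.54 (-1.60 and -2.31 at limits; adjusted p = 0.00463 and 0.0258). Among 12 receptor complex genes 1 rose and 3 fell, with the same counts adjusted over the list alone (fry adjusted p = 0.0154, adjusted p = 0.609 with an estimated correlation).

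The interferon list did not move 1 way: 2 of 22 members rose and 3 fell, with the same counts adjusted over the list alone (fry adjusted p = 0.438). Ifit3, an interferon-induced gene, fell by 2.03 ± 0.37 (-1.22 at limits), while Isg15, a ubiquitin-like interferon-induced protein, rose by 1.09 ± 0.16 (adjusted p = 0.0151 and 0.0079). Oas2, an interferon-induced gene outside the list, fell by 1.76 ± 0.27 (-1.08 at limits; adjusted p = 0.00901).

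Epithelial and stromal markers were also higher in gut, with 4 of 5 tested members up and 1 down, also adjusted over the list alone (fry adjusted p = 0.00318, adjusted p = 0.477 with an estimated correlation). Of the 25 measured markers of this list, 16 were at the floor in every sample. Cdh1 (E-cadherin) rose by 3.21 ± 0.41 and was above the floor in all gut samples and, at 5.41 and 5.38, in the mesenteric and peripheral CD8 samples. Epcam, an epithelial adhesion molecule, was 9.48 and 9.21 in lamina propria CD4 and CD8, 6.29 in intraepithelial CD8 and at the floor in intraepithelial CD4 and the nodes (adjusted p = 0.00818). Ceacam1 (7.74 and 7.83) and Ccl25 (7.28 and 6.91) were above the floor in the lamina propria samples only (adjusted p = 0.00338 and 0.00496). So was Dmbt1, a secreted epithelial glycoprotein outside the list (12.42 and 12.11, adjusted p = 0.000298). With a part of the gut samples and all node samples at the floor, no fold is given for these 4 genes. Pecam1, an adhesion molecule of endothelial cells that T cells also carry, was the member that fell. Among 5 myeloid markers Lyz2, the lysozyme of macrophages, was the 1 called higher (adjusted p = 0.00268; also the 1 member called adjusted over the list alone), and the list passed (fry adjusted p = 0.00946, adjusted p = 0.609 with an estimated correlation). Of the 26 measured myeloid markers, 19 were at the floor in every sample. Lyz2 was 9.52 and 8.98 in lamina propria CD4 and CD8 and at the floor in the intraepithelial samples. The gut calls of Ceacam1, Ccl25, Dmbt1 and Lyz2 thus rested on the lamina propria, and that of Cdh1 did not. Without genes at the floor in the intraepithelial CD4 and CD8 samples, 109 genes were called.

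The gut count of 125 fell to 65 without the mesenteric pair and 47 without the peripheral pair, and was 37 in a fit of gut against node with neither subset nor single tissues as terms. The floor of 6.30 for all samples ended the calls of Cd244, Ccl4, Ccl3, Ifit3 and Oas2. Median centring moved the median difference of all tested genes from 0.04 to -0.24 and gave 196 calls, of which 34.7% were higher in place of 54.4%.

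The third comparison divided the gut samples into intraepithelial and lamina propria. Gzma was higher in the intraepithelial samples by 4.25 ± 0.30, Gzmb by 3.51 ± 0.21 and Gzmk by 3.08 ± 0.61 (adjusted p = 0.00214, 0.00193 and 0.0272, higher in both subsets). Of 17 cytotoxic and NK-type genes, 8 rose and none fell, with 9 adjusted over the list alone (fry adjusted p = 0.00742, adjusted p = 0.347 with an estimated correlation). Fasl and Tnfsf10 (TRAIL), ligands of death receptors, rose by 2.40 ± 0.52 (1.765 at limits) and 2.35 ± 0.25. In all, 54 genes were higher and 42 lower among 440 tested.

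Itgae, whose product binds E-cadherin, rose by 2.91 ± 0.27 and Itga1 by 2.81 ± 0.52 (adjusted p = 0.00402 and 0.0231). With Cd160 these were the 3 of 10 residence genes that passed, 5 adjusted over the list alone (fry adjusted p = 0.0166, adjusted p = 0.368 with an estimated correlation). T cell receptor complex genes were higher too: 8 of 12 rose and 1 fell, also adjusted over the list alone (fry adjusted p = 0.00161, adjusted p = 0.347 with an estimated correlation). In the same contrast the epithelial and myeloid lists had medians of -2.775 and -1.08. The myeloid median was that of C1qbp, which does not mark myeloid cells, and Cd68 and Cybb of that list went the other way. The CD3 chain genes Cd3g and Cd3e rose by 1.32 ± 0.24 and 1.27 ± 0.17 and the kinase gene Fyn by 1.14 ± 0.09 (adjusted p = 0.0216, 0.0111 and 0.00297), while Cd2, an adhesion receptor of T cells, fell by 0.94 ± 0.21 (adjusted p = 0.0351). Of 22 interferon response genes, 6 rose, with 7 adjusted over the list alone (fry adjusted p = 0.033, adjusted p = 0.406 with an estimated correlation). They included Tapbp, of the class I loading complex, by 1.23 ± 0.19 (adjusted p = 0.0155). Il12rb2, a chain of the IL-12 receptor, rose by 2.69 ± 0.55 (2.055 at limits), Cd7 by 2.64 ± 0.35 and Amica1, a junctional adhesion molecule, by 2.46 ± 0.47.

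Naive and lymph node homing genes were lower in the intraepithelial samples, with 5 of 8 down; adjusted over the list alone, 5 were down and 1 up (fry adjusted p = 0.00564, adjusted p = 0.347 with an estimated correlation). Ccr7 fell by 3.52 ± 0.17 and Il7r by 1.21 ± 0.18 (adjusted p = 0.00142 and 0.0155).

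The epithelial genes went the other way, being higher in the lamina propria: 3 of 5 tested markers were lower in the intraepithelial samples, also adjusted over the list alone (fry adjusted p = 0.00161, adjusted p = 0.347 with an estimated correlation). Dmbt1, outside the list, was at least 96.3-fold lower there (adjusted p = 0.000274). Of the list, Ceacam1 was at least 4.32-fold lower and Ccl25 at least 2.68-fold (adjusted p = 0.00193 and 0.00299). Epcam fell by 4.04 ± 0.62 (-3.05 at limits; adjusted p = 0.0155), and Cdh1 did not pass (-0.57 ± 0.57, adjusted p = 0.558). Lyz2 was at least 11.9-fold lower, and 3 of 5 myeloid markers fell, also adjusted over the list alone (fry adjusted p = 0.00564, adjusted p = 0.406 with an estimated correlation). The others that fell were Cebpb and C1qbp, which lay at 7.30 to 8.88 in the 9 samples and does not mark myeloid cells. Cd68 and Cybb, of the same list, were higher in intraepithelial CD4 (6.44 and 7.47) than in lamina propria CD4 (5.01 and 5.58). Ifitm2, App and Cd63 were at least 3.52-fold, 3.25-fold and 2.24-fold lower. Of the 42 genes higher in the lamina propria, 12 were at the floor in all lymph node samples, and 11 of these also in the intraepithelial CD4 and CD8 samples.

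This contrast set 2 samples against 2, with the spread shared over the 8 samples. The 96 calls fell to 26 without the peripheral node pair and 54 without the mesenteric pair, to 20 without lamina propria CD4, to 10 without lamina propria CD8, and to 27 with sample weights. The floor of 6.30 for all samples ended the calls of Fasl and Il12rb2.

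The fourth comparison set the mesenteric against the peripheral nodes. No gene of 440 passed in limma (smallest adjusted p = 0.848), and 20 had an unadjusted p under 0.05. The spread was shared over the 8 samples here too, so the SE also held the variation of the gut samples. H2-Ea-ps, for example, was 6.99 and 6.31 in mesenteric CD4 and CD8 and 5.07 and 4.38 in peripheral CD4 and CD8. The lack of calls does not show that the nodes were alike. Sample weights gave 19 calls and the fit without a filter 1. The largest differences with 1 sign in both subsets were in class II genes, which were higher in the mesenteric samples: H2-Ea-ps by 1.93 ± 0.67, H2-Aa by 1.58 ± 0.64, H2-Ab1 by 1.53 ± 0.63 and Cd74 by 1.35 ± 0.49. Isg15 differed by 1.06 ± 0.22. On the lower side Abca1, a cholesterol exporter, differed by -1.32 ± 0.24, Fasl by -1.20 ± 0.52 and Dusp4, a phosphatase of MAP kinases, by -1.14 ± 0.39. No list passed (class II fry adjusted p = 0.212). Camera with its preset correlation called 3 lists higher in the mesenteric nodes, class II (adjusted p = 0.000184), interferon response (0.000899) and B cell markers (0.0274), and none held with an estimated correlation (each adjusted p = 0.448).

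The fifth comparison asked whether the CD8 minus CD4 difference was itself different in gut and lymph node. It was for 6 of 440 genes (94 at unadjusted p under 0.05), and in each the difference was lower in gut. Cxcr6, a chemokine receptor of tissue T cells, was 3.19 and 2.79 higher in CD8 than CD4 in mesenteric and peripheral nodes, and 0.76 and 0.64 lower in CD8 in the intraepithelial and lamina propria samples (adjusted p = 0.0214). Ccr9 was 3.01 and 3.49 higher in CD8 in the nodes and differed by 0.01 and -0.10 in the gut samples (adjusted p = 0.0303). Il2rb, the chain shared by the IL-2 and IL-15 receptors, differed by 1.38 and 1.54 in the nodes and by -0.07 and -0.33 in gut (adjusted p = 0.0341). In these 3 genes the gut CD4 samples were close to the CD8 samples, and the node CD4 samples were low.

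For Il17a and Il22, the Th17 cytokines, the gut CD4 samples were also above the node CD4 samples, but the CD8 samples were low. Il17a was 9.28 and 10.03 in intraepithelial and lamina propria CD4 and at the floor in every other sample, and Il22 was 9.67 and 11.36 there, 6.18 in lamina propria CD8 and at most 5.15 elsewhere (both adjusted p = 0.0303). Il18rap, a chain of the IL-18 receptor, was above the floor in gut CD4 (7.23 and 6.36) and in node CD8 (6.18 and 6.53), and at the floor in gut CD8 and node CD4 (adjusted p = 0.0424). With lamina propria CD8 taken at its limit, its difference there was -0.77 in place of -2.04. Of 13 Th17 genes Il17a and Il22 were the 2 that passed, and 12 passed adjusted over the list alone (fry adjusted p = 0.0448, adjusted p = 0.522 with an estimated correlation). Ccl20 and Il21 differed by -3.50 ± 0.50 and -3.29 ± 0.60 (-2.51 and -2.31 at limits; adjusted p = 0.0751 and 0.105). The Th1 list had 1 of 12 members past the test and 6 adjusted over the list alone (fry adjusted p = 0.0301, adjusted p = 0.522 with an estimated correlation), and the residence list 2 of 10, with 3 lower and 1 higher adjusted over the list alone (fry adjusted p = 0.0301, adjusted p = 0.821 with an estimated correlation).

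**Figure D2:**
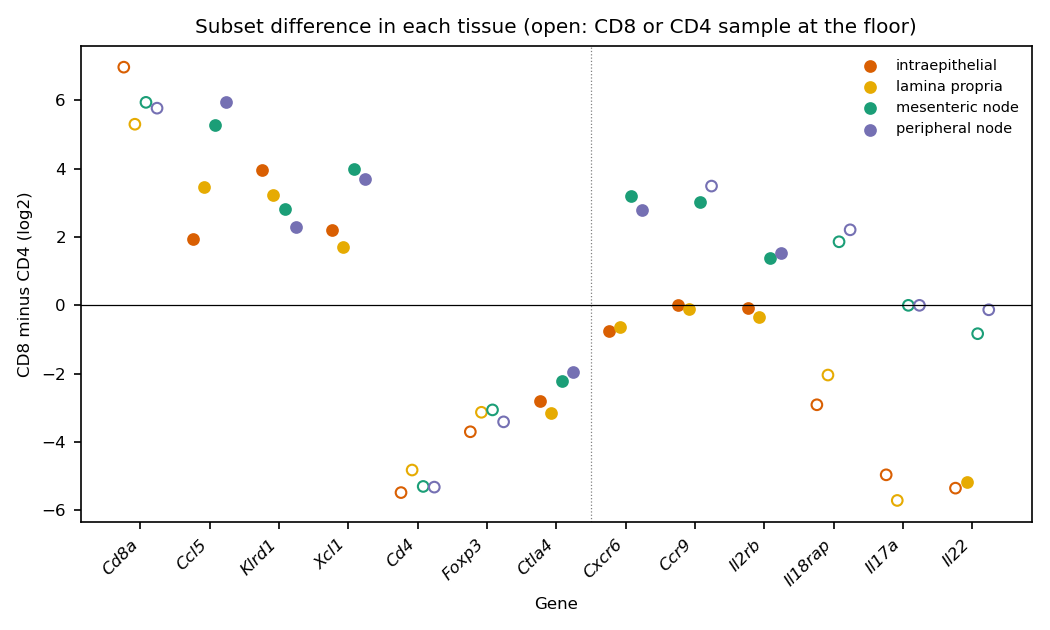
CD8 minus CD4 log2 difference of 13 genes in each of the 4 tissues, 1 point per tissue and gene, open where the CD8 or the CD4 sample was at the floor. Cxcr6 lay at 3.19 and 2.79 in the nodes and at -0.76 and -0.64 in gut, and Cd8a and Cd4 kept their sign in all 4 tissues.

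This fit had 2 residual degrees of freedom. Without any 1 of the 4 tissue pairs it called no gene, with all values below 6.30 raised to it 3 genes (the calls of Ccr9, Il22 and Il18rap ended), and without lamina propria CD4 or CD8 42 and 54 genes, of which 1 and 2 were among the 6 and 47.6% and 48.1% were higher in gut. The 1 gene called with no filter was none of the 6. The Il22 call ended with the raised floor though its gut CD4 values (9.67 and 11.36) lay far above 6.30. With values at limits its difference was -4.45, against -4.785 as listed. The 3 list calls became 0 with a pseudocount of 20, median centring, quantile normalization or the raised floor.

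The last comparison placed the intraepithelial CD4CD8 sample beside the intraepithelial CD4 and CD8 samples, with 1 sample each and no test. It carried Cd4 at 10.06 (9.80 in the CD4 sample) and Cd8a at 11.50 (11.29 in the CD8 sample). Cd8b1 was at the floor, below 5.52, against 8.85 in the CD8 sample. Its Gzma and Gzmb were the highest of the 9 samples, at 15.76 and 13.51, and Gzma made up 17.6% of its summed normalized counts. Ccl5 was 15.34, against 12.41 in CD4 and 14.36 in CD8.

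Among genes differing by at least 1 log2 between the intraepithelial CD4 and CD8 samples (79 genes, values below 6.30 raised to it), the CD4CD8 sample was nearer to CD8 in 56 and nearer to CD4 in 23. Of the 53 genes higher in CD4, it was nearer to CD4 in 18. Of the 26 higher in CD8, it was nearer to CD8 in 21. Most of the 56 were thus genes of the CD4 sample that were lower in CD4CD8. Its median difference from CD4 over the 17 cytotoxic and NK-type genes was 1.27, above all of 10000 random lists matched on mean level (percentile 100; list values here also use the raised floor of 6.30), and from CD8 it was 0.00 (percentile 26.3). The chemokine list was 1.555 above CD4 (percentile 99.98). Random lists were drawn gene by gene, so these and later percentiles can be too extreme for genes that vary together. Th17 genes lay 1.23 below CD4 (percentile 0 of the random lists): Il17a, Il22, Il23r, Il17f, Il1r1 and Ccl20 were at the floor, and Il21 and Ccr6 were 7.01 and 6.20 against 8.65 and 7.62 in CD4. Regulatory genes lay 1.015 below CD4 (percentile 0.05), with Foxp3 at the floor. Ctla4 was 10.51, between CD4 (11.44) and CD8 (8.63), and so was Icos at 8.60 (10.69 and 6.92).

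Naive and lymph node homing genes lay below both samples, by a median of 0.69 against CD4 (percentile 0.85) and 0.485 against CD8 (percentile 0.05). Class II genes lay 1.09 above CD8 (percentile 100) and 0.07 below CD4 (percentile 26.6). Cd74 was 9.68, against 9.84 in CD4 and 6.96 in CD8, and H2-Aa was 8.75, 8.99 and 6.09 in the same order. Some other genes of antigen-presenting cells, chosen after their values were seen, went the same way. Ctsh, Ly86, Cd180, Cd68 and Cybb were 6.87, 6.69, 6.20, 6.01 and 5.90 in CD4CD8 and 7.11, 6.44, 6.68, 6.44 and 7.47 in CD4. They were at the floor in CD8. The fixed myeloid list, which holds Cd68 and Cybb, had a median of 0.00 against CD8 (percentile 43.9) with values below 6.30 raised to it, a floor above most of these values.

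By listed values 19 genes were at least 1 log2 above both other samples and 11 at least 1 log2 below both. The 10 farthest above (Itga2, Ccrl2, Klra17, Serping1, Atg7, Il3ra, Itgb3, H2-Eb1, Egr2 and Irf5) were 5.66 to 6.20 in CD4CD8 and at the floor in the other samples, and every one lay under the limit of 6.30 of the CD4 sample, so none of these is known to be higher than in CD4. With each value at the floor taken at its sample's limit, a rule chosen after the data were seen, 5 genes lay above both: Gzma, Gzmb, Ifng, Lgals3 (galectin-3) and Cd6. Gzmb exceeded the nearer sample 2.40-fold and Ifng 2.30-fold. By the same rule 3 genes lay below both: Tcf7 (7.54, against 9.87 in CD4 and 9.78 in CD8), Il7r (7.03, 8.80 and 8.71) and Itgb1, the beta-1 integrin chain (5.66, 7.15 and 7.32). The others of the 10 farthest below by listed values were Ccr7, Psen2, Cd2, Ncf4, Bcl6, Atg10 and Slamf6, all at the floor in CD4CD8.

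**Figure D3:**
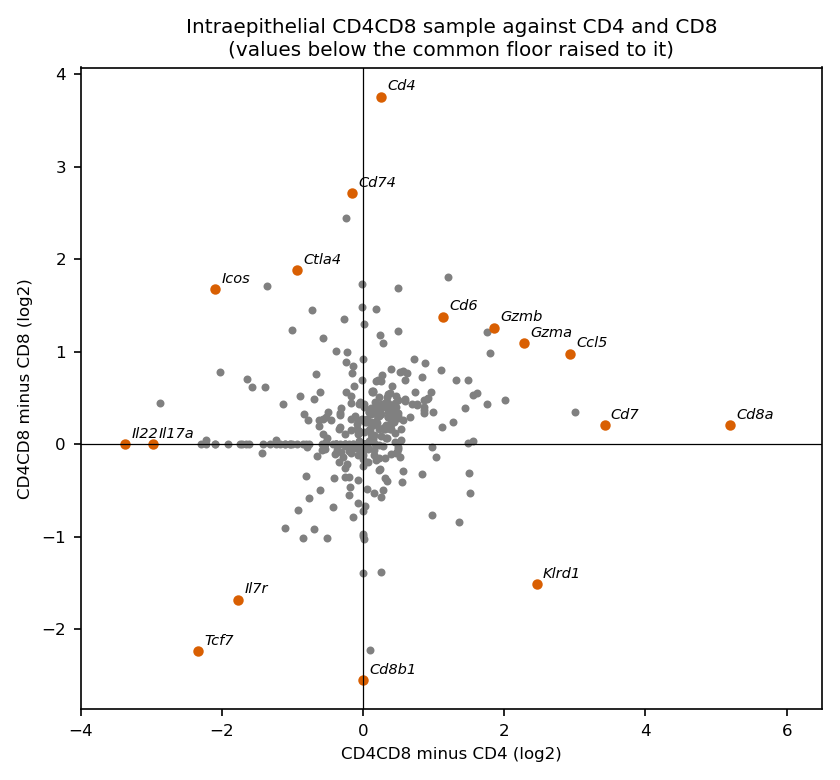
Difference of the intraepithelial CD4CD8 sample from CD4 (x axis, log2) and from CD8 (y axis, log2), 1 point per gene, values below 6.30 raised to 6.30, named genes in orange. Gzma, Gzmb and Cd6 lay above 1 on both axes, Tcf7 lay lowest on the diagonal, and Il22 and Il17a were far left of 0 with no difference from CD8.

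The remaining lists passed in none of the tested comparisons by fry: immediate-early and NF-kB response (lowest adjusted p = 0.0781, for the change of the subset difference between gut and node), B cell markers (0.17 in gut against lymph node, 0.32 between nodes), and common gamma chain cytokine receptors (0.0514, intraepithelial against lamina propria). The CD8 lineage list passed between subsets (fry adjusted p = 0.00792, adjusted p = 0.254 with an estimated correlation; 2 of 4 higher, 3 adjusted over the list alone), and the CD4 lineage list, with 2 measured genes, was not tested. For 14 tests of a list, none past the threshold, the median, the mean and the fry direction were not of 1 sign (an exact median of 0 counted among them): naive, interferon and epithelial genes between subsets, the CD8 lineage and Th2 genes between gut and node, the CD8 lineage and B cell markers between gut compartments, residence, inhibitory and epithelial genes between nodes, and cytotoxic, naive, epithelial and gamma chain genes for the change of the subset difference. Besides the receptor complex list, 14 list medians over the 5 comparisons, none of a list past the threshold, changed sign with median or housekeeping centring.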

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

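The tests of explanations and the splits of samples below were chosen or written down after the results were seen, and are tests, not predictions, while the fit of the subset difference between gut and node was fixed beforehand.

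The CD8 minus CD4 difference was itself different in gut and in lymph node for 6 genes, by an added term in the fit. The difference in gut less that in node was -3.69 for Cxcr6, -3.295 for Ccr9, -1.66 for Il2rb, -5.335 for Il17a, -4.785 for Il22 and -4.51 for Il18rap (log2, 1 sample per tissue and subset). The last 3 move most with values at the floor: with each such sample at its limit, the difference was -4.32 for Il17a, -4.45 for Il22 and -3.465 for Il18rap, while Ccr9, with peripheral CD4 at the floor, moved by under 0.1. No technical or biological explanation was tested for these.

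Epithelial genes stood out in both lamina propria samples. The test took 10 genes above 6.30 in at least 1 of them and at the floor in the node and intraepithelial CD4 and CD8 samples. They were picked without the fit and not for being epithelial. Their median absolute CD8 minus CD4 difference was 0.34. Of them 7, Dmbt1 among them, were within 0.5, as epithelial cells or their RNA carried into both samples would give. The other 3 (Cxcl2, Cxcl3 and Lif) were higher in CD4. Expression by both T cell subsets would also give similar levels, so this cannot tell the 2 apart. Of 11 genes that the fit called higher there and that were at the floor in those other samples, unequal detection limits were argued against for 6, which lay above the highest limit in both samples, and stay open for 5. Myeloid cells as the source of Lyz2 stay open: Lyz2 lay at least 3.39 above the limit, C1qa, C1qb and Csf1r were at the floor, and Apoe, a macrophage gene chosen after its values were seen, was 6.26 and 6.32. Carry-over of epithelial material could account for these genes, and expression by lamina propria T cells, a difference the tissues name, was not tested.

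Cd4 and Cd8a stood together in the intraepithelial CD4CD8 sample without Cd8b1. Doublets or a mixture of cells like those of the CD4 and CD8 samples were argued against, as an equal mixture would hold Cd8b1 at 7.91, which is 2.39 above the sample's limit. A mixture of all the cells of the CD4 sample with CD8 cells lacking Cd8b1 was argued against by the abundant genes: over the 13 that were at the floor in CD8 and at least 2 log2 above the limit in CD4, Cd4 itself left out, the sample lay a median of 1.55 below an equal mixture. Over all 38 genes above the floor in CD4 and at the floor in CD8, the median was 0.56. Of these, 7 were at or above the mixture. Most lay within 2 log2 of the limit, where only a small shortfall can be seen, so this median cannot decide. Cd4 (10.06) and Cd8a (11.50) lay above the CD4 and CD8 samples (9.80 and 11.29), while an equal mixture of those samples would lower both. These 2 values are from 1 sample, and a mixture with a part of the CD4 cells, without Th17 and regulatory cells, was not excluded. A population with CD4 and CD8 alpha-alpha is a hypothesis, and protein data that would test it were not analysed here.

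Gzma, Gzmb and Ccl5 were high in the intraepithelial CD4 sample (13.48, 11.66 and 12.41). CD8a-expressing cells or their RNA as the source were argued against: over 11 cytotoxic genes, a source of any 1 of them would bring Cd8a at least 1.02 above the limit (median 3.55), and Cd8a was at the floor. Cells with neither CD4 nor CD8 could not be told apart from CD4 cells here, since Cd4 lay 0.33 above the mean of the other CD4 samples and the scaling between tissues is unknown. A place-specific program of CD4 cells was not tested and stays open.

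Other splits of the samples gave the following. With tissue as a block, the 64 genes for CD8 against CD4 were reached by 1 of 8 splits, the real one (highest other 0), and moving the gut and node labels within subsets gave 61 genes for the real split, reached by 1 of 18 splits (highest other 0); these splits are too few for a share under 0.05. Without a block, 2 of 35 splits reached the 21 genes for CD8 against CD4, so chance was not excluded there. The highest other split gave 37 genes and was the division into gut and node, a structure of the samples. That division was reached by 1 of 35 splits (37 genes, highest other 21), a share under 0.05, but these splits ignore that samples are paired by tissue and subset, so chance is not taken as excluded for it.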

How the results depend on the processing

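The alternatives were fixed before the data were examined, except the common floor, single samples left out, values at the limit, and fits without genes at the floor in a compartment, which were chosen after. A pseudocount of 20 kept the gene counts of the 5 tested comparisons within 1.5 times. CD8 against CD4 (64 genes) gave 14 with no filter, 158 with sample weights, 21 with no block, 36 with a common floor of 6.30, and 22 to 69 without 1 tissue pair or 20 to 66 without 1 sample. Gut against node (125) gave 196 with median centring, 37 with no block, and 47 to 141 without 1 pair or 65 to 190 without 1 sample. Intraepithelial against lamina propria (96) gave 48 with no filter, 27 with sample weights, and 26 to 54 without 1 node pair or 10 to 104 without 1 sample. Mesenteric against peripheral (0 in limma, 20 at unadjusted p under 0.05) gave 1 with no filter and 19 with sample weights. The change of the subset difference (6) gave 1 with no filter, 3 with the common floor, 0 without any 1 pair, and 0 to 54 without 1 sample. Fewer samples and, with no filter, more genes at the floor are part of these settings by construction; for the others the cause was not tested.

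Lists passing by fry numbered 7, 9, 7, 0 and 3 in the same order. With genes of more than 1 list left out they numbered 6, 8, 7, 0 and 3. Camera with an estimated correlation gave 0 in all 5; with its preset correlation it gave 5 for gut against node and 3 between nodes. The 3 lists for the subset difference became 0 with the pseudocount of 20, median centring, quantile normalization or the common floor, 0 to 2 without 1 pair and 0 to 1 without 1 sample. Between nodes 1 list passed with no filter, and 0 to 1 without 1 pair or sample. Leaving out 1 sample gave 0 to 7, 5 to 11 and 4 to 6 lists in the first 3 comparisons, and leaving out 1 pair 1 to 7 for CD8 against CD4. For the CD4CD8 sample, 19 genes above and 11 below both became 9 and 7 with the pseudocount of 20, 0 and 2 at a threshold of 2 log2, 5 and 3 with values at the limit, and 5 and 2 with the common floor. Lyz2 in gut against node turned to -0.06 without the lamina propria pair, and was 4.87 without the intraepithelial pair, which shows where its difference came from. edgeR, DESeq2 and voom were not run, as the file holds no raw counts. Low signal limits what can be said of genes under 6.30, the limit of intraepithelial CD4.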

Other observations

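The gene tests in this part were fixed before the data were examined. The genes named were picked, after their values were seen, from members of the fixed lists past the threshold, and the correlations were added after the data were seen.

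Some single genes are not described above. Nt5e, the CD73 ectoenzyme that makes adenosine, rose by 1.07 ± 0.12 in gut against node and again by 1.04 ± 0.17 in the intraepithelial against the lamina propria samples (adjusted p = 0.00496 and 0.0193). Tigit, an inhibitory receptor, rose by 1.38 ± 0.34 in gut (adjusted p = 0.0383, a call that ended with all values below 6.30 raised to it). Cxcl10, an interferon-induced chemokine, rose by 1.73 ± 0.41 (adjusted p = 0.0339). Il12rb1, the shared chain of the IL-12 and IL-23 receptors, was higher in intraepithelial than lamina propria samples by 2.005 ± 0.32 (1.37 with lamina propria CD8 at its detection limit; adjusted p = 0.0157), beside its partner Il12rb2. Tap1, a peptide transporter, was higher there by 0.75 ± 0.13 and Psmb8, a proteasome subunit, by 0.62 ± 0.11 (adjusted p = 0.0193 and 0.0209).

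Between samples, the mesenteric and peripheral nodes were nearest each other (correlation across genes 0.988 for CD4 and 0.989 for CD8). The intraepithelial CD4CD8 sample correlated at 0.949 with intraepithelial CD8 and at 0.910 with intraepithelial CD4. These correlations took all 770 genes, of which 267 were at the floor in every sample, and such shared floor values raise them.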
